A study of Mus musculus with 27 samples.

How the data were processed

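The series holds 27 samples from mouse MC38 tumours (MC38 is a colon adenocarcinoma cell line). Tumour-associated macrophages, or CD45-positive immune cells, were taken from mice with a floxed Ogt gene (called WT) and from mice that also carried the Lyz2-cre transgene, which deletes floxed genes in myeloid cells (called KO). Ogt encodes O-GlcNAc transferase, the enzyme that adds O-GlcNAc to proteins. The groups were taken from the sample titles. RNA-seq of macrophages had 3 WT and 3 KO samples. Single cell RNA-seq of CD45-sorted cells had 2 samples per genotype but 1 matrix per genotype. CUT&Tag against the transcription factor EGR2 had 3 WT and 3 KO samples and 1 peak list per genotype, and ATAC-seq, which measures open chromatin, had 3 WT and 3 KO samples and 1 merged peak list. EGR2 ChIP-seq (1 WT sample), H3K27ac (2 WT samples) and H3K4me1 (2 samples whose title and genotype field name different genotypes) were not analysed here.

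For RNA-seq, the authors gave raw counts per gene, made per the file headers with featureCounts 2.0.6 on GENCODE vM10 gene models. The header options counted each read of a pair, ignored the strand and left out multi-mapped reads, so that reads of near-identical genes (Lyz1 and Lyz2, Hspa1a and Hspa1b, class I H2 genes, Trbc1 and Trbc2) are assigned only where they differ. Between 83.95% and 89.08% of genes with low counts had an even count, as counting both reads of a pair gives. For single cells, the authors gave UMI counts per barcode from Cell Ranger 8.0.1 per the file headers, with all barcodes included. The deposited peak lists give a score per peak, with peaks 501 bp wide, 1 list per genotype for EGR2. The score sums to 992722 over the WT list and 991547 over the KO list, so it compares peaks within a list. The peak caller, read trimming and alignment settings are not given in the sources used here. The submitters' processing notes name mm10 as the genome build.

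RNA counts were tested with edgeR 4.0.16 (quasi-likelihood F-test, 2-sided, filterByExpr, TMM) in R 4.3.3, KO against WT, and genes with a Benjamini-Hochberg adjusted p below 0.05 were called. Of 48440 gene identifiers, 48058 (99.2%) had a symbol in the name table. Expression is given as CPM (counts scaled to a common library total, TMM-normalised), mean ± SD with n = 3 libraries per genotype, and log2 fold changes are KO over WT with their standard error (SE). A gene at 0 in all WT libraries gets a lower bound on its fold, against a floor of 3 read pairs (6 counts, since each read of a pair is counted) over the 27425939 counts of the WT group. Total counts per library ran from 7032540 to 32406170. On simulated counts of the same depth, the test called 70%, 94% and 100% of genes changed 1.5-, 2- and 4-fold (50 each), and 5 of 12464 unchanged genes. Gene lists were tested with camera in limma 3.58.1 (2-sided, preset correlation 0.01, adjusted over 25 lists), with camera on an estimated correlation beside it. The fry test was run as well; it asks whether a list's genes move 1 way on balance, and does not compare them with other genes as camera does.

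There were 26 gene lists and 18 lists of cell type markers. The lists, the groups, the tests, the rule for named genes and most alternatives were fixed before the data were examined. By the rule, the named genes are Ogt, the 10 largest called rises and falls, and up to 4 called members per list with the smallest adjusted p. The rises and falls needed a mean of at least 1 log2 CPM and 3 KO values on 1 side of the WT values. Predicted genes, pseudogenes, receptor segments, Y-linked genes and Xist were left out of them. In single cells they are Ogt, Egr2 and the 8 largest ratios each way per class, among genes with at least 100 UMIs and at least 20 CPM in 1 matrix, without mitochondrial and haemoglobin genes. Other named genes were chosen after their values were seen and are said to be.

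Cells with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs were kept, and doublets called by Scrublet were removed. Both matrices were clustered together with scanpy 1.11.5 (2000 variable genes, 30 components, 15 neighbours, Leiden resolution 1) under Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and scikit-learn 1.9.0. A cluster was named after the class with the best marker score if at least 3 markers were found in at least 20% of its cells, if its leading genes held no more markers of another class, and if the 2 best scores lay at least 0.05 apart. That gap was first 0.1. It was lowered to 0.05 after the first result had been seen, because a cluster led by Ccl7, Arg1, F13a1 and Mrc1 (scores 1.24 for macrophages and 1.16 for monocytes) had stayed unnamed, and the size of the difference in the macrophage-like share depends on it. UMIs were summed per class and matrix as CPM, with a pseudocount of 5 CPM in log2 ratios. Median ratios of lists were placed among 10000 random lists matched on expression. With 1 matrix per genotype there is no replicate and no test. Intervals are 95% exact (Clopper-Pearson or Poisson) and cover counting error only. Barcodes under 100 UMIs gave the level of free RNA. In a simulation with 33696 genes, a list of 25 genes raised 1.5-fold gave a median log2 ratio of 0.53 at percentile 100, against percentile 70.2 for unchanged genes.

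EGR2 peaks were called shared when they overlapped a peak of the other genotype by at least 1 bp, and were compared with peaks moved at random within their chromosome (100 shuffles). On a list with planted overlaps, all 1622 planted of 5408 peaks were found, with 11 others among the random ones. The peak coordinates were checked against the gene starts of the count files. On 19 of 20 chromosomes, peaks and gene starts coincided most often after a shift of 11600 to 956400 bp (2289 pairs at the best shifts, 297 at no shift). The EGR2 and ATAC lists lined up with each other at a shift of 0. The build of the peak lists is therefore open, and comparisons that need peaks and genes in 1 build were left out: peaks at gene starts, peaks at the Egr2 and Ogt loci, gene names of peaks, and the RNA change of genes near peaks found in WT alone.

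Alternatives for RNA were the replicate number as a block, each of the 6 libraries left out, RLE size factors, other filters on low counts, DESeq2 1.42.0, limma voom and a minimum fold. For peaks they were other overlap rules and score limits. For single cells they were other cell filters, doublets kept, Leiden resolutions 0.5 and 2, pseudocounts of 1 and 20 CPM, and cells thinned to 1000 UMIs. Alternatives added after seeing the data were counts divided into read pairs, Lyz2 left out, a test against 1.5-fold (glmTreat), the score gap of 0.1, clustering without the genes called in bulk at 2-fold, and adding unnamed clusters with macrophages among their 2 best classes. No pairing of libraries by replicate number was seen: residuals of libraries with the same number correlated at -0.00484 to 0.0112 across genes, against -0.0101 to 0.00921 for the other pairs. Spread within a genotype was near counting noise for most genes, so this check cannot exclude a pairing.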

Results

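The data cover tumour-associated macrophages and CD45-sorted immune cells of MC38 tumours, compared between WT and KO mice as defined above. The 3 WT macrophage RNA libraries held 12439582, 7953817 and 7032540 counts, and the 3 KO libraries held 32406170, 11468556 and 12156594. The single cell matrices held 85755359 UMIs in WT and 85418469 in KO, from which 9716 WT cells and 9755 KO cells were kept, with median depths of 5580 and 5805 UMIs. The EGR2 lists held 5408 peaks in WT and 4995 in KO, and the merged ATAC list held 30189. The labels do not say which animals the libraries came from.

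The macrophage RNA comparison asks what differs in tumour macrophages of mice with floxed Ogt and Lyz2-cre. Ogt (ENSMUSG00000034160.13, X, 101640060 to 101684351) fell from 56.3 ± 6.24 to 34.7 ± 3.86 CPM (log2 fold change -0.72, SE 0.0953, adjusted p = 2.978e-09, n = 3 per genotype). The count covers the whole gene, and the labels do not say which exons are floxed. Reads outside the deleted part may remain, so the Ogt RNA left in KO does not measure how much intact Ogt is left. Lyz2 (ENSMUSG00000069516.7, chromosome 10, 117277334 to 117282274), the lysozyme gene whose locus carries cre in this mouse line, fell 46.2-fold, from 3882 ± 53.8 to 84.0 ± 1.52 CPM. KO mice thus differ from WT by cre and by most of their Lyz2 RNA as well as by the Ogt deletion. The design cannot tell these apart, so no difference between the genotypes can be credited to Ogt alone. Egr2 (ENSMUSG00000037868.15, chromosome 10, 67535475 to 67542188), the transcription factor named in the study's title, fell 1.87-fold, from 265 ± 9.54 to 143 ± 10.6 CPM (adjusted p = 9.478e-28). Genes of alternative activation, chemokines and cholesterol synthesis fell together, while genes of MHC class I presentation and markers of T and NK cells rose.

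In all, 4874 of 12939 tested genes were called (37.7%), 2432 higher and 2442 lower in KO. Most changes were small: 3161 of the called genes (64.9%) changed less than 1.5-fold, and 728 changed at least 2-fold, 455 upward and 273 downward. For 6022 of the tested genes (46.5%) the 3 KO values all lay on 1 side of the 3 WT values, which chance gives for 10% of genes, and 4560 of these were called.

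Among the 10 largest rises, 3 genes had no count in any WT library: BC043934 was at least 23.9-fold higher in KO (5.24 ± 0.665 CPM), Ip6k3, an inositol phosphate kinase, at least 17.1-fold (3.75 ± 0.61 CPM), and Tspan7, a tetraspanin, at least 14.9-fold (3.27 ± 0.432 CPM). Gpx3 (chromosome 11, 54902453 to 54910377), a secreted glutathione peroxidase, rose from 7.74 ± 1.28 to 78.3 ± 0.863 CPM (log2 fold change 3.35, SE 0.115, adjusted p = 9.709e-37). Gstt1, a glutathione transferase, rose from 0.795 ± 0.442 to 12.5 ± 1.03 CPM (4.02 on the log2 scale). The others were Tmem229a (5.54), St6galnac5 (5.34), Clic5 (4.48), Slc17a6 (3.39) and Rgs8 (3.27), each below 6 CPM in KO. Besides Lyz2, the largest falls included Cebpb (chromosome 2, 167688915 to 167690418), a transcription factor of myeloid cells, which fell from 735 ± 33.8 to 151 ± 18.9 CPM (-2.28, SE 0.0404, adjusted p = 5.237e-54). Mmp9 (chromosome 2, 164940780 to 164955850), which encodes a matrix metalloproteinase, fell from 52.2 ± 3.61 to 9.46 ± 1.5 CPM (-2.42, SE 0.123). Pxdc1 fell from 107 ± 10.7 to 22.8 ± 4.2 CPM (-2.26). The remaining large falls were Ccdc80 (-2.53), Glcci1 (-2.29), S100a9 (-2.17), Dsel (-2.17), Siglecf (-2.15) and Ifnb1 (-2.14), each below 8 CPM in WT.

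**Figure D1:**
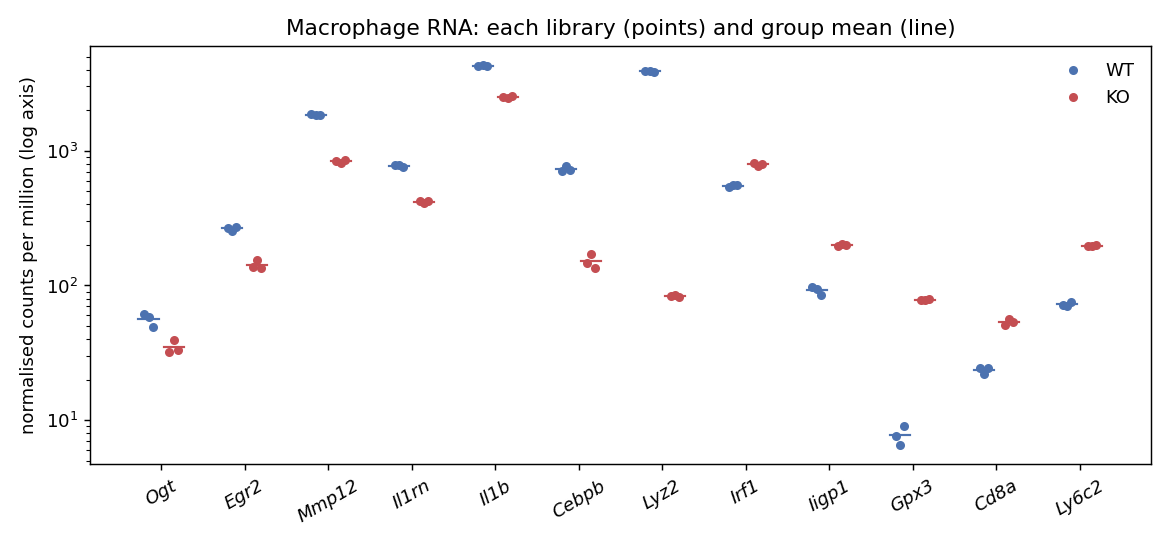
Normalised CPM (log axis) of 12 genes in each of the 3 WT and 3 KO macrophage RNA libraries (points), with the group mean (line). For each gene the 3 KO values lie on 1 side of the 3 WT values, with the widest gap for Lyz2 (3882 CPM in WT, 84.0 in KO).

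Of 27 measured genes of alternative, protumoral activation, 19 fell and 5 rose, with the same counts adjusted over the list alone (camera adjusted p = 3.19e-20, and adjusted p = 0.0289 with an estimated correlation). Mmp12, the macrophage elastase, fell from 1848 ± 11.1 to 837 ± 18.5 CPM, Il1rn, the interleukin 1 receptor antagonist, fell 1.84-fold, Fn1 (fibronectin) 1.67-fold and Clec7a, the beta-glucan receptor, 1.57-fold. Of 23 genes of proinflammatory activation, 11 fell and 6 rose, also adjusted over the list alone (adjusted p = 0.00504, and adjusted p = 0.0703 with an estimated correlation). The cytokine genes Il1b (4265 ± 60.5 to 2508 ± 54.8 CPM) and Il1a (-1.88 on the log2 scale) fell, as did Socs3 (-0.30), an inhibitor of cytokine signalling, while the transcription factor Irf1 rose (0.52). Of 20 chemokine genes 13 fell and 3 rose, and 14 fell adjusted over the list alone (adjusted p = 1.83e-16, and adjusted p = 0.0289 with an estimated correlation). Cxcl1 fell 2.9-fold and Ccl22 2.76-fold, and Cxcl2 and Ccl6 fell by 0.71 and 0.60 on the log2 scale. Ccl22 is also a marker of migratory dendritic cells, and 3 other such markers, Ccr7, Fscn1 and Cacnb3, fell 2.57-fold, 2.33-fold and 3.05-fold in the same libraries. In the interferon response 11 of 29 genes rose and 8 fell, also adjusted over the list alone (adjusted p = 0.00234, and adjusted p = 0.0703 with an estimated correlation). The 4 members with the smallest p were GTPases induced by interferon: Iigp1 (2.16-fold higher), Igtp (1.87), Irgm1 (1.77) and Gbp3 (1.63). Markers of T and NK cells rose in the same libraries (median log2 fold change 0.88).

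Antigen presentation by MHC class I rose: 12 of 15 genes were higher and 1 lower, with the same counts adjusted over the list alone (adjusted p = 2e-06, and adjusted p = 0.0289 with an estimated correlation), in libraries in which T and NK cell markers also rose. The rises were small, as for H2-K1 (1.18-fold), B2m (1.17-fold), the peptide transporter Tap1 (1.23-fold) and the loading chaperone Pdia3 (1.37-fold). In MHC class II presentation 4 of 11 genes rose and 5 fell, with 6 falls adjusted over the list alone (adjusted p = 0.672; median log2 fold change -0.03, mean 0.00245). H2-DMb2 fell by 0.36 on the log2 scale, H2-Ab1 and H2-Aa fell by 0.10 each, and Ctss, a protease that processes the invariant chain, rose by 0.14.

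All 16 called genes of the 18 in cholesterol synthesis fell, with the same count adjusted over the list alone (median log2 fold change -0.67, adjusted p = 1.04e-14, and adjusted p = 0.0289 with an estimated correlation). They included Hmgcs1 (1.84-fold lower), Insig1 (1.68) and Cyp51 (1.67). Of 24 genes of glycolysis and hypoxia, 16 fell and 2 rose, also adjusted over the list alone (adjusted p = 1.43e-05, and adjusted p = 0.0639 with an estimated correlation). The genes Pgk1, Ndrg1, Ero1a and Ldha fell by 0.45, 0.56, 0.69 and 0.27 on the log2 scale. Of 22 lysosome genes, 12 rose and 6 fell, with 13 rises adjusted over the list alone (adjusted p = 0.0201, and adjusted p = 0.383 with an estimated correlation). Ctsb, Hexa and Ctsa rose by 0.32, 0.51 and 0.38 on the log2 scale, and Ctsl, another cathepsin, fell by 0.85. Without WT replicate 3 the lysosome list had an adjusted p of 0.0597 (0.00291 to 0.0227 under the other alternatives with the preset correlation). In lipid handling 4 of 16 genes rose and 7 fell, also adjusted over the list alone (adjusted p = 0.888). There Lpl (lipoprotein lipase) and the fatty acid receptor Cd36 rose by 0.91 and 0.80, and Apoe and Fabp5 fell by 0.56 and 0.61. In complement and efferocytosis 5 of 15 genes rose, among them Cd93 (0.90) and Stab1 (0.32), and 7 fell, among them C3ar1 (-0.52), with the same counts adjusted over the list alone (adjusted p = 0.592; median -0.04, mean 0.04). In oxidative phosphorylation 5 of 22 genes rose and 4 fell, also adjusted over the list alone (adjusted p = 0.918; the median was -0.03 and the mean -0.02, while the camera direction was up). Its members with the smallest p were Atp5a1 (0.26), Ndufa2 (-0.54), Mdh2 (-0.18) and Cox4i1 (0.18).

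Of 5 measured EGR family and corepressor genes, Egr2, Egr3 (-0.76) and Egr1 (-0.42) fell, also adjusted over the list alone (adjusted p = 0.00346, and adjusted p = 0.0853 with an estimated correlation). Of 19 dissociation and immediate early genes, which also respond to handling of tissue, 15 fell and 3 rose, with the same counts adjusted over the list alone (adjusted p = 3.51e-07, and adjusted p = 0.0668 with an estimated correlation). The genes Junb, Fosb, Hspa1a and Hspa1b fell by 0.49, 0.35, 0.32 and 0.28 on the log2 scale. In the OGT and hexosamine list 2 of 12 genes rose and 5 fell, with 3 rises adjusted over the list alone (adjusted p = 0.592). Besides Ogt, Oga, which encodes the enzyme that removes O-GlcNAc, fell by 0.41 and Renbp by 0.33, and Gfpt1, the first enzyme of the hexosamine pathway, rose by 0.30. In the integrated stress and unfolded protein response 10 of 17 genes fell and 2 rose, with 11 falls adjusted over the list alone (adjusted p = 0.00749, and adjusted p = 0.0795 with an estimated correlation). The genes Manf, Xbp1, Herpud1 and Atf4 fell by 0.53, 0.48, 0.40 and 0.34. In the cell cycle 9 of 25 genes rose and 2 fell, with 10 rises adjusted over the list alone (adjusted p = 0.254). The mitotic kinase gene Plk1, Mcm6 and Bub1b rose by 1.13, 0.52 and 0.50, and E2f1 fell by 0.50. In the p53 response 4 of 15 genes rose and 4 fell, also adjusted over the list alone (adjusted p = 0.888; median -0.02, mean 0.03). In it Plk2 and Mdm2 rose by 0.40 and 0.24, and Bbc3 and Cdkn1a fell by 0.79 and 0.40.

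**Figure D2:**
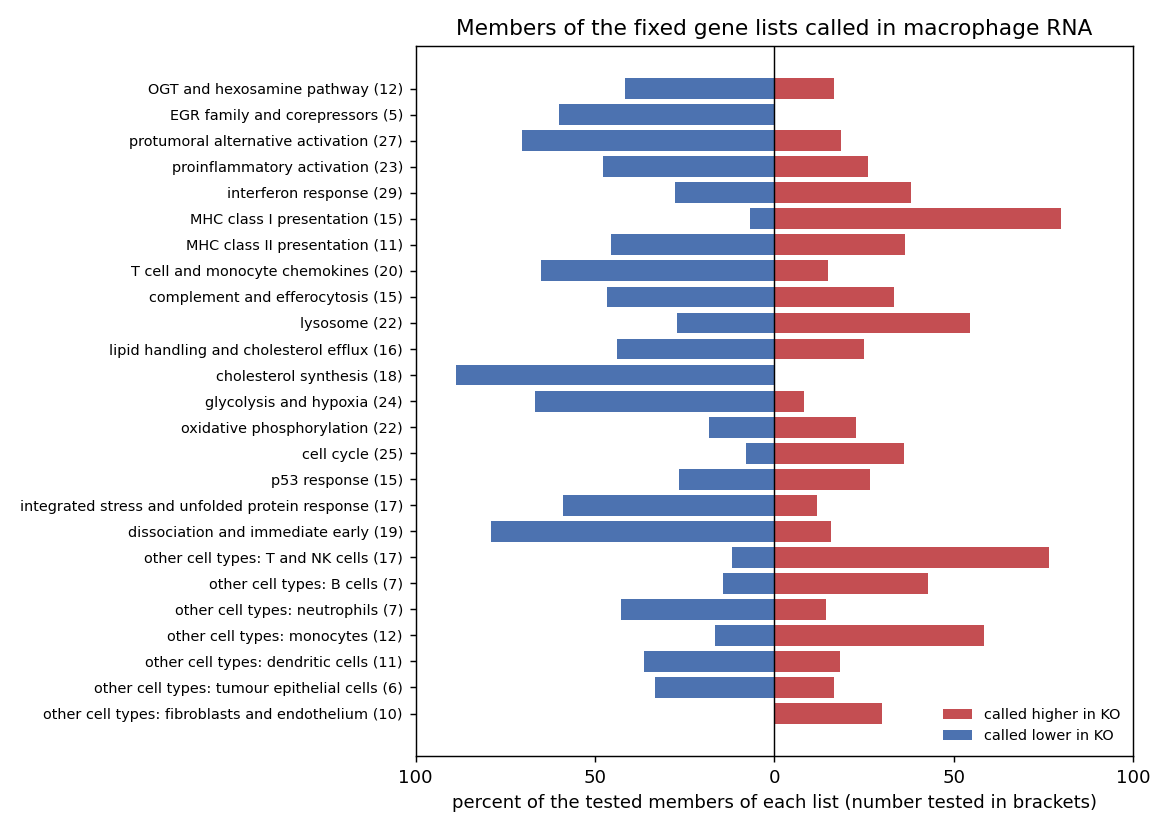
Percent of the tested members of each gene list called higher (right) or lower (left) in KO macrophage RNA, with the number tested in brackets. In cholesterol synthesis 16 of 18 genes were lower and 0 higher, and in MHC class I presentation 12 of 15 were higher and 1 lower.

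Markers of other cell types moved with genotype. Of 17 T and NK cell genes, 13 rose and 2 fell, also adjusted over the list alone (median log2 fold change 0.88, adjusted p = 1.26e-06, and adjusted p = 0.0289 with an estimated correlation). The T cell coreceptor gene Cd8a rose 2.26-fold, to 53.6 ± 2.75 CPM (log2 fold change 1.18, SE 0.101), Nkg7 2-fold, Cd3g 1.99-fold and Trbc1 1.84-fold. Of 12 monocyte genes 7 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.000226, and adjusted p = 0.0592 with an estimated correlation). The genes Ly6c2, Ccr2 and Plac8 rose by 1.45, 0.57 and 0.41, and Nr4a1 fell by 0.43. Of 7 B cell genes, Cd79a (2.67), Igkc (1.91) and Ighm (1.15) rose and Cd79b fell (-0.90), also adjusted over the list alone (adjusted p = 0.0298, and adjusted p = 0.137 with an estimated correlation). Of 11 dendritic cell genes 2 rose and 4 fell, with 3 rises adjusted over the list alone (adjusted p = 0.0205, and adjusted p = 0.155 with an estimated correlation). That list lost its call without a filter on low counts (adjusted p = 0.0751) and with counts divided into read pairs (0.0837), against 0.0124 to 0.0313 under the other alternatives with the preset correlation. Xcr1, a marker of cDC1, rose by 1.66, and Ccr7, Fscn1 and Cacnb3, markers of migratory dendritic cells, fell by 1.36, 1.22 and 1.61. Of 7 neutrophil genes 1 rose, Csf3r (0.24), and 3 fell, S100a9, Cxcr2 (-1.79) and Mmp8 (-0.67), also adjusted over the list alone (adjusted p = 0.592). Of 6 epithelial genes Krt18 rose (1.27) and Cdh1 (-0.70) and Epcam (-1.58) fell, also adjusted over the list alone (adjusted p = 0.592). Of 10 fibroblast and endothelial genes Col1a1 (2.49), Kdr (1.11) and Pecam1 (0.26) rose and 0 fell, also adjusted over the list alone (adjusted p = 0.149, and 0.0457 to 0.164 under the alternatives with the preset correlation, lowest with counts divided into read pairs). Of the erythroid and mast cell list too few genes were measured for a test; Kit had 22.3 ± 1.64 CPM in WT and 22.6 ± 2.56 in KO (adjusted p = 0.9165). The calls of Cd79b, Cxcr2, Mmp8, Epcam and Pecam1 were each lost without at least 1 library (adjusted p up to 0.245, for Cxcr2 without WT replicate 2).

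Of 25 lists tested, 15 passed camera and 5 passed it with an estimated correlation. Spread was lower between libraries of 1 genotype than between genotypes: for genes with 20 to 200 counts, the mean chi-square per gene was 2.66 to 3.33 within a genotype and 4.53 to 6.22 between genotypes. It was 2.66 to 3.45 and 10.9 to 14.7 for 200 to 2000 counts, 2.70 to 3.76 and 42.6 to 71.8 for 2000 to 20000 counts, and 3.98 to 44.9 and 690 to 950 above that. Counting alone gives about 1 for independent counts and about 2 where each read of a pair is counted, so the spread within a genotype was near counting noise except in the most abundant genes. The p-values measure only the spread between these libraries, and the labels do not say that it includes spread between animals or that the libraries did not come from pooled material.

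In the CD45-sorted cells, the comparison asks how immune cells and macrophage states differ with genotype. CD8 T-like cells made up 10.9% of WT cells (95% interval 10.3 to 11.5) and 15.5% of KO cells (14.8 to 16.2), a ratio of 1.42. The CD8 T-like shares were 18.7% and 19.9% under a looser cell filter (ratio 1.07), 17.1% and 19.5% with doublets kept (1.14) and 19.4% and 20.4% at Leiden resolution 0.5 (1.05), so the size of this difference rests on the settings too. Left out of the class was an unnamed cluster led by S1pr1, Lef1 and Tcf7, which scored 0.752 for CD8 T and 0.742 for CD4 T cells. That cluster went the other way, with 7.05% of WT and 4.46% of KO cells. CD4 T-like cells made up 5.66% and 8.01%, regulatory T-like cells 10.3% and 11.3%, and NK-like cells 14.7% (14.0 to 15.4) and 11.3% (10.7 to 12.0). Macrophage-like cells made up 25.6% of WT cells (24.8 to 26.5) and 23.9% of KO cells (23.0 to 24.7), and monocyte-like cells 10.5% and 9.26%. A further unnamed cluster, with 4.22% of WT and 4.54% of KO cells, is not in the macrophage-like class. It scored 0.994 for macrophages and 0.108 for monocytes, but its leading genes held more markers of another class. Those leading genes included Mmp12, Mgl2, Ccl24, Arg1 and Fn1, which are on the protumoral list. Values of the macrophage-like class leave this cluster out unless unnamed clusters are said to be added. The macrophage-like shares were 19.2% in WT and 14.6% in KO under the score gap of 0.1 used at first, and 26.6% and 26.5% under a looser cell filter, so the size of this difference rests on the settings.

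Neutrophil-like cells made up 6.24% of WT and 7.77% of KO cells, gamma-delta T or innate lymphoid-like cells 1.68% and 1.83%, cDC1-like cells 0.967% and 0.707%, plasmacytoid dendritic-like cells 0.422% and 0.215%, and B-like cells 0.319% and 0.42%. Unnamed clusters held 12.0% and 9.44%. Under the stricter filter the neutrophil-like shares were 2.37% and 3.41%. The cDC1-like shares were 2.84% and 2.65% under the looser filter, 2.27% and 1.84% under the stricter filter, 2.36% and 1.97% with doublets kept, and 1.82% and 1.39% at resolution 0.5. At resolution 0.5 and without bulk genes no cluster was named plasmacytoid. Unnamed clusters held 18.5% and 18.7% under the score gap of 0.1, where KO was the higher. They held 21.8% and 20.3% without bulk genes, 10.3% and 6.84% at resolution 2, 7.90% and 5.56% under the stricter filter, and 3.62% and 2.14% under the looser one. With doublets kept and at resolution 0.5 no cluster stayed unnamed. With 1 matrix per genotype, no difference in shares could be tested against spread between mice.

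**Figure D3:**
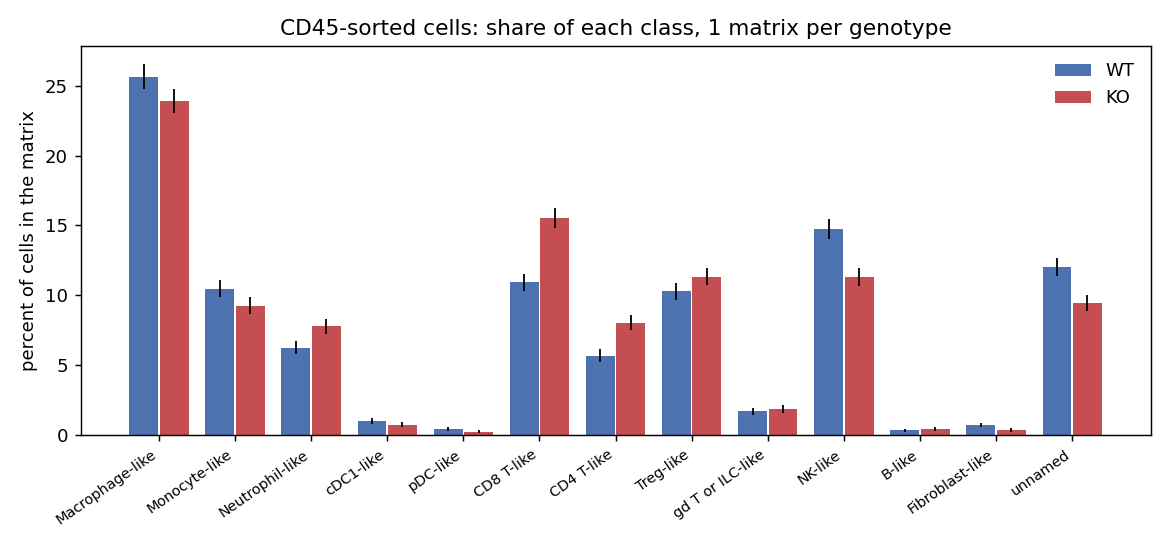
Percent of the cells of each matrix in each class, for WT (9716 cells) and KO (9755 cells); bars show the share and lines its 95% exact binomial interval, which covers counting error only. CD8 T-like cells made up 10.9% in WT and 15.5% in KO, and NK-like cells 14.7% and 11.3%.

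Within the macrophage-like class, a cluster led by the MHC class II genes H2-Eb1, H2-Ab1 and H2-Aa held 57.5% of WT and 40.2% of KO cells. A cluster led by Ccl7, Arg1, F13a1 and Mrc1 held 25.2% of WT and 38.8% of KO cells. The 2 clusters led by complement C1q genes held 12.8% and 14.9%, and 4.46% and 6.09%. In the summed UMIs of macrophage-like cells, Lyz2 was at 3031 CPM in WT and 12.8 in KO (free RNA 1291 and 14.0). Egr2 was at 170 CPM (164 to 176) in WT and 132 CPM (126 to 137) in KO, with 95.9 and 81.5 in free RNA. By cluster, Egr2 was at 168 and 166 CPM in the one led by MHC class II genes and at 198 and 184 in the one led by Ccl7. It was at 163 and 65.0 CPM in the larger C1q cluster, where the KO value lay below free RNA. In the smaller it was at 42.0 and 15.1, both below free RNA (13 and 7 UMIs). The median share of UMIs from dissociation and immediate early genes was 3.20% in WT and 2.31% in KO cells. Ogt was at 50.4 CPM (47.2 to 53.7) and 41.8 CPM (38.9 to 44.8), below the free RNA levels of 98.5 and 107. UMIs are likewise counted per gene and not per exon, so they do not measure intact Ogt either. The largest rises were Lyz1 (5.62 to 123 CPM), Nos2, the inducible nitric oxide synthase (6.37 to 51.2), and Cox4i2 (6.15 to 46.5). They were followed by Lpl (19.96 to 106), Tnfrsf9 (11.1 to 62.3, below its free RNA levels of 213 and 508), Cd36 (29.9 to 127), Ch25h, a cholesterol hydroxylase (3.96 to 25.8), and Iigp1 (73.2 to 261). Besides Lyz2, the largest falls were G0s2 (106 to 21.1, below its free RNA levels of 260 and 203), Mid1 (88.1 to 18.2), Ear2 (26.7 to 5.71, with free RNA levels of 23.2 and 13.2), Bank1 (21.1 to 4.45), Hes1 (237 to 83.2), and the heat shock co-chaperones Dnajb1 (658 to 238, below its free RNA levels of 781 and 398) and Bag3 (292 to 106). The fall of Mid1 was not particular to macrophage-like cells. Mid1 also went from 119 to 16.7 CPM in CD8 T-like cells and from 62.9 to 11.6 in free RNA.

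Of 26 gene lists, 9 had a median ratio outside the central 95% of random lists of like expression in macrophage-like cells. These medians come from UMIs summed over 4 clusters whose shares of the class differ between the matrices. The cluster led by MHC class II genes, for example, held 57.5% of the WT and 40.2% of the KO cells of the class. A different mix of clusters could move a median without a change inside any cluster, and no list was measured within clusters. All 15 MHC class I genes were higher in KO (median log2 ratio 0.30, percentile 99.99), as were 21 of 24 glycolysis and hypoxia genes (0.31, percentile 100), 23 of 25 cell cycle genes (0.34, percentile 100), 17 of 22 lysosome genes (0.34, percentile 100) and 11 of 17 lipid handling genes (0.20, percentile 99.2). With cells thinned to 1000 UMIs the cell cycle list lay inside the range (0.14, 16 of 25 genes higher, percentile 94.2). The lipid handling list lay inside it under 3 of 11 alternatives: a pseudocount of 20 CPM (percentile 80.8), the score gap of 0.1 (91.1) and clustering without genes called in bulk (95.9). All 19 dissociation and immediate early genes were lower (-0.58, percentile 0), with 11 of 18 cholesterol synthesis genes (-0.08, percentile 0.49), 10 of 12 monocyte genes (-0.23, percentile 0.07) and 9 of 11 neutrophil genes (-0.11, percentile 0.28). The cholesterol list lay inside the range with cells thinned (0.01, 9 genes higher and 9 lower, percentile 19.7), with doublets kept (percentile 9.53) and with unnamed clusters added (3.18). The neutrophil list lay inside it with cells thinned (3.72), under the looser filter (25.2) and with doublets kept (0.0051, percentile 60.5). The other 5 lists stayed outside under all 11 alternatives. Protumoral activation was at 0.14, inside the range (percentile 93.2), but above it under 7 of 11 alternatives (percentiles 98.5 to 100, with medians of 0.16 to 0.24), and at -0.02 (percentile 5.43) under the score gap of 0.1. Proinflammatory activation was at -0.03 (percentile 7.58), and below the range under the stricter filter (-0.06, percentile 1.14) and without bulk genes (-0.09, percentile 0.39). The interferon response was at 0.14 (percentile 91.6). It lay above the range under the score gap of 0.1 (0.25, percentile 99.8) and without bulk genes (0.27, percentile 100), and below it under the stricter filter (-0.03, 14 genes higher and 15 lower, percentile 1.16). The EGR family was at 0.0022 (percentile 32.4). The other medians were 0.09 for the hexosamine list (percentile 55.5), 0.02 for MHC class II (71.9), 0.04 for chemokines (59.8, and 99.98 with cells thinned), 0.10 for complement (94.5), 0.13 for oxidative phosphorylation (84.5), -0.02 for p53 (18.9, and 2.24 with doublets kept) and 0.07 for the integrated stress response (68.0). Markers of T and NK cells were at 0.15, inside the range (percentile 97.3), but above it under 9 of 11 alternatives (percentiles 99.1 to 100, with a median of up to 0.55 under the stricter filter). Among markers of other cells the medians were -0.0078 for B cells (19.1), 0.01 for dendritic cells (31.0), -0.02 for epithelial cells (27.3), 0.02 for fibroblasts (60.2) and -0.02 for erythroid and mast cells (59.3, but 0.76 under the looser filter and 0.07 with doublets kept).

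In CD8 T-like cells, which are outside the myeloid lineage that Lyz2-cre targets, Ogt was at 106 CPM in WT (100 to 112) and 120 CPM in KO (115 to 126), beside free RNA levels of 98.5 and 107, and Egr2 at 8.36 and 6.56 CPM, below free RNA. The largest rises were Tex11 (0 UMIs in WT, which allows up to 0.33 CPM, and 67.3 CPM in KO), Gzmf, a granzyme gene (135 to 592), Serpine2 (28.0 to 124) and Il17a (2.34 to 21.4, below free RNA). Next were the NK receptor genes Klri2 (12.4 to 50.9, with free RNA levels of 33.6 and 35.3) and Klrh1 (8.72 to 34.3), and Spp1 (50.3 to 149) and Lmna (29.6 to 81.7), both below free RNA. The largest falls were Lyz2 (39.7 to 0.14 CPM, 2 UMIs in KO, and below free RNA), Mid1 (119 to 16.7), the cytokine Il13 (26.8 to 2.37, with free RNA levels of 5.20 and 6.70), the TNF family ligand Cd70 (28.9 to 8.17), Cdk5rap1 (21.2 to 5.24, with free RNA levels of 15.6 and 5.71), the chemokine Ccl1 (78.7 to 31.0, with free RNA levels of 63.45 and 29.1), Aff3 (25.3 to 8.17, below free RNA) and Hspb1 (137 to 59.6, with free RNA levels of 153 and 47.1).

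The macrophage-like cells and the macrophage RNA libraries were compared gene by gene. Of 4108 genes called in the libraries and measured in the cells, 2906 (70.7%, 95% interval 69.3 to 72.1) had the same sign. The share was 83.0% of those higher in KO and 59.0% of those lower. Across genes, which are not independent replicates, Pearson's r was 0.44 and Spearman's rho 0.50. Over all 9773 measured genes the shares were 63.0% together, 76.6% of those higher and 49.4% of those lower, with a median log2 ratio of 0.07 in the cells, so the split between rises and falls is not special to called genes. Of 24 glycolysis and hypoxia genes, 16 were called lower in the libraries, in a list that did not pass with an estimated correlation, and 21 were higher in the cells. The 12 monocyte genes also went opposite ways. In the libraries 7 were called higher and 2 lower, in a list that did not pass with an estimated correlation either, and 10 were lower in the cells. Of the protumoral genes, 19 of 27 were called lower in the libraries, and 19 of 28 were higher in the cells, but 13 of 28 under the score gap of 0.1. Chosen after their values were seen, Mmp12 had 457 CPM in WT and 694 in KO cells, and Cebpb 3572 and 3125, against falls of 2.21-fold and 4.87-fold in the libraries.

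The EGR2 peak lists ask where this factor sits in chromatin in WT and KO mice. Of 5408 WT peaks, 618 (11.4%, 95% interval 10.6 to 12.3) overlapped a KO peak, against 0.211% of shuffled peaks. Of 4995 KO peaks, 612 (12.3%, 11.4 to 13.2) overlapped a WT peak. Sharing rose with the score: 77.8% of the top 1% of WT peaks and 75.5% of the top 1% of KO peaks were shared, against 6.47% and 6.21% of the 50% with the lowest score. EGR2 peaks overlapped an ATAC peak by any length more often in WT (1451 peaks, 26.8%, 25.7 to 28.0) than in KO (580 peaks, 11.6%, 10.7 to 12.5), against 1.198% and 1.15% of shuffled peaks. Among peaks found in 1 list alone the shares were 26.5% in WT and 9.17% in KO, and among shared peaks 29.8% and 29.1%. The ATAC list held 17476 peaks named for WT and 12713 named for KO. A single peak on chromosome 2 held 31.7% of the WT score (98494987 to 98495487) and another 50.6% of the KO score (98496206 to 98496706), in the lists' own coordinates, whose build is open. Each of these was counted as found in 1 list alone, and each overlapped an ATAC peak. They lie in the same stretch, however. Between 98492699 and 98497322 both lists had peaks of high score whose windows missed each other. One of these was a WT peak at 98496822 to 98497322, close to the top KO peak. Being found in 1 list alone therefore does not show a signal particular to 1 genotype there. The top 3 peaks held 66.3% of the WT score and 64.6% of the KO score, and 1 ATAC peak held 24.2% of the ATAC score. Regions of extreme signal were not removed, and whether the highest scores mark EGR2 was not tested. With 1 list per genotype over 3 samples, neither the sharing of peaks nor the difference in ATAC overlap could be tested, and the depth behind the lists is unknown.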

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

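No test in this part was chosen after a result was seen. Fibroblast-like cells, which a sort for CD45 should leave out, made up 0.7% of the cells in the WT matrix (68 cells) and 0.338% in the KO matrix (33 cells). No comparison of the report rests on them, although they are 1 of the classes behind the class-specific genes of the other observations. Their number shows only that they were present. The cluster's leading genes were Tm4sf1, Serpinh1, Rhox5, Col3a1, Krt8 and Krt18. Krt8 and Krt18 are markers of the epithelial tumour class, so the cluster may hold tumour cells, and its name rests on the marker score alone.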

How the results depend on the processing

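Chosen after seeing the data were counts divided into read pairs, Lyz2 left out, the test against 1.5-fold, the score gap of 0.1, clustering without genes called in bulk, and the added unnamed clusters. The count of 4874 called genes stayed within 3991 to 4587 with 1 library left out (3875 to 4207 shared), and within 4792 to 5142 under RLE factors, other filters, read pairs, no Lyz2, DESeq2 and limma voom; no shared gene changed sign. It was 728 with a fold of at least 2 and 503 in the test against 1.5-fold, both stricter by construction. The Ogt log2 fold change ran from -0.80 to -0.65 over 14 alternatives, each called. With the replicate number as a block 4691 genes were called, 4677 of them shared. No pairing by these numbers was seen, but the check could not exclude it. Of 115 named genes, 5 lost their call without 1 library (10 values, against 680 that kept it), and all 918 values under the other settings kept direction and call. Lists past camera fell from 15 to 5 with an estimated correlation, and numbered 14 to 15 with 1 library left out. By fry, which tests each list against no change and not against other genes, 20 passed, so that count is not on the same scale.

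Overlap of WT and KO EGR2 peaks moved to 6.69% and 7.25% (reciprocal overlap of 50%), 15.8% and 17.1% (centres within 1 kb) and 13.3% and 14.2% (top-scored 50% of each list). The share overlapping ATAC peaks was 39.3% and 15.7% in the top-scored 50%, against 14.4% and 7.53% in the lowest-scored 50%. It fell to 15.5% and 6.55% with an overlap of 50%, a rule stricter by construction. WT stayed above KO. Not run, because the peak lists' build is open, were peaks at gene starts, the RNA change of genes near EGR2 peaks, and all their alternatives.

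Macrophage-like shares in WT and KO were 19.2% and 14.6% with the gap of 0.1, used first and then lowered; 26.6% and 26.5% with the looser filter; 30.5% and 28.8% with the stricter one; 30.9% and 29.4% with doublets kept; 30.6% and 28.7% at resolution 0.5; 27.7% and 26.7% at resolution 2; and 17.1% and 14.1% without bulk genes. CD8 T-like shares moved to 18.7% and 19.9% (looser filter), 17.1% and 19.5% (doublets kept) and 19.4% and 20.4% (resolution 0.5), so their ratio fell from 1.42 to as low as 1.05. Macrophage-like stayed lower and CD8 T-like higher in KO throughout. Genes of like sign in cells and libraries were 62.7% with cells thinned to 1000 UMIs, 72.3% with the gap of 0.1, 68.2% with doublets kept and 72.8% without bulk genes. Lists outside the central 95% numbered 8 to 13. Of 9 lists outside, 5 were outside under all 11 alternatives, and of 17 inside, 10 stayed inside. Of 286 list medians under the alternatives, 8 came inside and 24 went outside with their sign kept. Another 24 changed sign, and in 3 of them the list lay outside before or after: cholesterol synthesis at 0.0109 with cells thinned, neutrophil genes at 0.0051 with doublets kept, and the interferon response at -0.0293 with the stricter filter. The cause of these moves was not tested.

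Depth limits genes under about 1 CPM in the libraries, and 1 matrix or list per genotype leaves the cell shares and peaks without a replicate.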

Other observations

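Of the tests in this part, those of a lower macrophage share, of gene length, of a few genes taking counts and of other splits were chosen after the result was seen, and those of T and NK cell RNA and of dissociation before. Clusters within the T cells moved in different directions. A CD8 T-like cluster led by Cd8a, Gldc, Serpine2 and Pdcd1, the gene of the checkpoint receptor PD-1, held 3.89% of WT cells (3.52 to 4.29) and 6.99% of KO cells (6.49 to 7.52). A CD8 T-like cluster led by Gzmk, Ccl5 and Fasl held 4.27% and 5.87%, and the one led by cell cycle genes such as Mki67 and Birc5, held 2.75% and 2.65%, within counting error. An unnamed cluster led by S1pr1, Lef1 and Tcf7, genes of resting T cells, held 7.05% of WT (6.55 to 7.58) and 4.46% of KO cells (4.06 to 4.89).

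Among monocyte-like cells, a cluster led by the interferon-induced genes Ifit2, Mx1, Cxcl11 and Rsad2 held 4.15% of WT (3.76 to 4.56) and 2.35% of KO cells (2.06 to 2.67), while one led by Chil3 and Ace held 6.32% and 6.91%. Il1b was at 2957 CPM in WT and 2039 in KO monocyte-like cells, 4664 and 3179 in macrophage-like cells, and 12600 and 12070 in neutrophil-like cells. Egr2 was lower in KO monocyte-like cells (59.95 and 41.8 CPM) and higher in KO neutrophil-like cells (33.7 and 53.9 CPM), all below the free RNA levels of 95.9 and 81.5. Arg1, a gene of alternative activation, was at 171 CPM in WT and 429 in KO macrophage-like cells, with 71.9 and 158 in free RNA. Most of its UMIs came from the cluster led by Ccl7 and Arg1 (656 and 1149 CPM), which is in the class only under the lowered score gap. Arg1 went from 61.5 to 169 CPM in the cluster led by MHC class II genes and from 60.7 to 140 in the larger C1q cluster, with WT values below free RNA in both and the KO value below it in the latter. It fell from 223 to 115 CPM in the smaller C1q cluster (69 and 53 UMIs). These genes and clusters were chosen after their values were seen, and none of these differences could be tested.

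In the macrophage libraries the real split called 4874 genes and the highest of the other splits 0 (85 to 227 at an unadjusted p under 0.05, edgeR). Only 1 of the 10 splits gave as many, and 10 splits are too few for a share under 0.05. Each of the other splits put libraries of both genotypes in both groups, where a difference between genotypes adds to the spread within groups. Few calls are then likely whatever the cause of that difference, so the 0 does not tell causes apart.

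T and NK cell markers rose in the KO macrophage libraries. A lower share of macrophages would raise genes of all other cells alike, but 12 genes at least 20-fold higher in neutrophil-like cells than in every other class had a median log2 fold change of -0.45 (bootstrap interval -1.34 to -0.11), while 6 cDC1 genes had a median of 0.50 (0.07 to 1.43). These intervals over genes do not meet, but they cannot decide the question, because the neutrophil set may not measure neutrophils. The genes of B-like (0.82, -0.68 to 2.67), plasmacytoid-like (0.40, -0.49 to 0.85) and fibroblast-like cells (0.27, -0.02 to 0.52, 63 genes) had intervals that span 0. The neutrophil set includes Hcar2 and Acod1, which macrophages can also express. It summed to 478 CPM in the WT libraries, where S100a9, a leading gene of neutrophil-like cells, had 3.85 ± 2.12 CPM. A lower share of macrophages therefore stays open. More T and NK cell RNA in the KO libraries may account for the rise and stays open: 12 genes as specific to T and NK cells, from outside the list, had a median of 0.59, but 8 were higher (66.7%), with an interval of -1.22 to 0.91, and their summed CPM went from 139 to 106. A change within these cells, and the higher CD8 T-like share in the KO tumours, stay open as well and were not tested.

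Ribosomal protein genes, a group chosen after the data were seen, fell in KO: 76 of 84 were called lower and 0 higher in the macrophage libraries (median log2 fold change -0.54), and 72 of 80 were lower in macrophage-like cells (median -0.20). Short genes fell more than long ones, but random lists of like length and expression had a lowest 2.5% bound of -0.22, and 0% of 10000 lists lay below the observed median. A few genes taking most of the counts would lower all other genes by a common factor, while the ribosomal protein genes lay 0.41 below the median of those random lists (-0.13, difference -0.4098). The group was chosen after its values were seen, so a place below random lists was likely from the start. How closely the lists match such short and abundant genes was not measured. The values show that these genes fell more than the genes drawn, and neither comparison decides the cause. Lower ribosomal protein mRNA in KO macrophages is a hypothesis, and differences in library preparation or cell handling between the genotypes may also account for it and were not tested.

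Egr2 was lower in KO in macrophage-like cells (log2 ratio -0.36) and in the libraries. Cells of the KO matrix also held fewer UMIs of 18 dissociation and immediate early genes (median 2.31%, against 3.20% in WT). Compared within 5 groups of like share of those UMIs, the Egr2 log2 ratio averaged 0.0341 (counting interval -0.05 to 0.12), but ran from -0.63 in the lowest group to 0.57 in the highest, and an average over groups that go both ways decides nothing. By cluster, the log2 ratio was -0.02 and -0.10 in the 2 largest macrophage-like clusters, and -1.26 and -1.22 in the C1q clusters (the last on 13 and 7 UMIs). In both C1q clusters the KO value lay below free RNA. A different dissociation response may account for lower Egr2 in single cells and stays open. Egr2 is itself induced by the same stimuli, so a lower activation of KO macrophages in the tumour would look the same and stays open too. For the libraries, where dissociation genes also fell, no such grouping can be had.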
